A study of Homo sapiens with 12 samples.

How the data were processed

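Poly(A) RNA from HT29 and HCT116 cells, wild type or labelled FTO knockout, was sequenced in 12 libraries, 3 per group, from fragments whose second strand was marked with dUTP and removed, per the labels' protocols. The deposited tables, 1 per line, list 37205 genes with an FPKM value per library, per the file headers. They also hold the authors' ratio of knockout over wild type, its log2, and a p-value and q-value per gene, per the file headers. The authors' ratio was checked on the values: in 100% of genes it equals the ratio of the mean FPKM of the groups, with a mean of 0 replaced by 0.0001. The aligner, the counting tool, the annotation, the use of strand in counting and the test behind the authors' deposited p-values are not given in the sources used here. The genome build is mm10, a mouse build, per the submitters' processing notes, although the gene identifiers are human and 36066 of them (96.9%) were found in GENCODE release 29, whose coordinates (GRCh38), GC content and transcript lengths were used. The titles of the deposited tables carry the letters sh before FTO, whereas the labels and the study design describe a CRISPR/Cas9 knockout.

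Read counts were not among the values used here. The step between the lowest FPKM values of genes with 1 exon placed the depth at 17.3 to 20.3 M fragments per library, if 1 step stands for 1 fragment, but only 20.4% to 23.7% of low values lay within 0.05 of a whole multiple of that step, where chance gives 10%, so counts were not recovered. The planned test for counts was therefore replaced by the one planned for normalized values. FPKM values were transformed as log2(FPKM + 1), genes with a mean of at least 0.5 FPKM over the 6 libraries of a line were kept, and limma-trend (limma 3.58.1 in R 4.3.3) compared knockout with wild type in each line. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The difference between the lines was the interaction term of 1 fit over the 12 libraries. On this scale the fold change of a gene near or below 1 FPKM is understated.

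Groups of genes were tested with camera (two-sided, preset correlation 0.01) on 33 lists, adjusted over the lists with at least 5 tested members, which were 31 in HT29 and 30 in HCT116. Camera with a correlation estimated per list and fry were the alternatives. Overlap of the calls of the 2 lines was tested with Fisher's exact test, two-sided, among the genes tested in both. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named FTO, the 5 largest rises and 5 largest falls per line among called genes with a symbol, a mean of at least 1 FPKM and groups that do not overlap, up to 3 called members with the smallest adjusted p of each of the 8 lists with the smallest camera p, the 5 genes per direction with the smallest adjusted p of the difference between lines, and the 5 per direction called in both lines with the smallest larger p. Some genes that the rule named are not reported here. Other members of lists given as examples were chosen after their values were seen. Levels of 1 gene on the X chromosome and of genes on the Y chromosome are not reported.

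Alternatives planned were the replicate number as a block, libraries shifted to a common median of log ratios, no filter on low values, a mean of at least 1 FPKM, each library left out in turn, 1 fit for both lines, limma without the trend and a pseudocount of 0.1. Alternatives chosen after seeing the data were the removal of each library's trend over GC content and transcript length (splines with 5 degrees of freedom) and FPKM divided by its sum per library (TPM). The tests were run first on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In HT29 (13550 genes) 81% of 2-fold and 94% of 4-fold changes were recovered, in HCT116 (13906 genes) 84% and 93%, and for the difference (14320 genes) 72% and 88%. False calls were 6.9%, 6.3% and 4.8% of all calls, and a planted shift of 1 list was called with no other list called. The simulated noise was independent between genes. The list result therefore does not cover lists whose members vary together, such as the HT29 ribosomal protein list (estimated correlation 0.82). A planted GC trend in HT29 gave 978 calls before the correction and 0 after it. The trend was planted on the same GC values that the correction uses, so other forms of GC bias were not tested. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.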

Results

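Poly(A) RNA was sequenced from HT29 and HCT116, a pair of human colorectal carcinoma lines, to follow what loss of FTO does to gene expression. FTO is a demethylase that removes N6-methyladenosine (m6A), a methyl mark on adenosines inside mRNA. HT29 cells can take on features of enterocytes and mucus-secreting goblet cells, and HCT116 cells are poorly differentiated. Each line was measured as wild-type cells and as cells labelled FTO knockout, with 3 libraries per group and 12 libraries in all. The labels call the libraries biological replicates but do not say whether they came from separate cultures or whether the knockout cells were a pool or 1 clone, so the p-values measure only the spread between these libraries. Expression was given as FPKM for 37205 genes per library. Genes above 0 numbered 23811 to 25006 per HT29 library, 24409 to 24986 per HCT116 wild-type library and 26022 to 27012 per HCT116 knockout library. Mitochondrially encoded genes held 23.2% to 25% of all FPKM in HT29, 41.7% to 42.9% in HCT116 wild type and 38.8% to 40.4% in HCT116 knockout.

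FTO itself (ENSG00000140718, chromosome 16, 53701692 to 54158512, GRCh38) was lower in every library labelled knockout than in every wild-type library of its line. In HT29 it stood at 0.172 ± 0.0184 FPKM (SD, n = 3) in the knockout and 1.57 ± 0.165 in the wild type (SD, n = 3), which is 9.16-fold lower. In HCT116 it stood at 0.236 ± 0.0174 FPKM in the knockout and 2.21 ± 0.230 in the wild type (SD, n = 3 each), which is 9.36-fold lower. On the log2(FPKM + 1) scale, which understates the change of a gene at this level, the log2 fold change was -1.13 ± 0.09 (SE) in HT29 (limma adjusted p = 0.000629) and -1.37 ± 0.09 in HCT116 (limma adjusted p = 0.000194). The authors' deposited tables give a log2 fold change of -3.19 for HT29 and -3.23 for HCT116. FTO did not reach 0 in any library, and a gene-level value does not show which exons the remaining fragments came from.

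**Figure D1:**
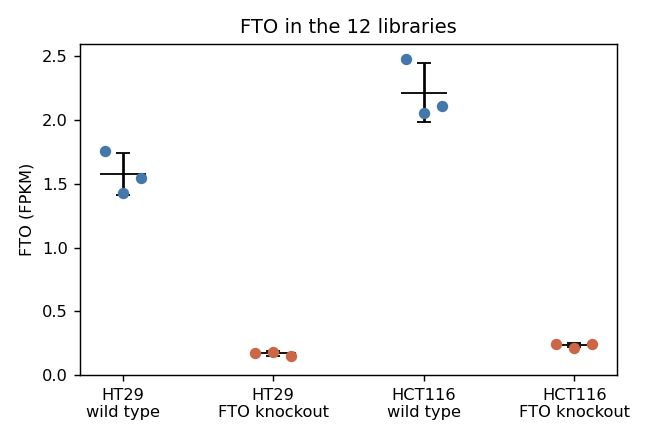
FTO in FPKM (vertical axis, starting at 0) in each of the 12 libraries, by line and genotype label. Points are libraries, and the bar and whiskers are the mean and SD of 3 libraries. The knockout libraries lie at 0.151 to 0.187 in HT29 and 0.216 to 0.249 in HCT116, below all wild-type libraries, which start at 1.43 and 2.06.

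The comparison of knockout with wild-type HT29 asked which genes follow the loss of FTO in a line with enterocyte and goblet features. Under the naming rule and on the log2(FPKM + 1) scale, the largest fall was that of CXCR4, the receptor of the chemokine CXCL12. It fell from 16.9 ± 0.721 to 1.96 ± 0.0878 FPKM (SD, n = 3 each), a log2 fold change of -2.60 ± 0.06 (SE, limma adjusted p = 1.14e-06). NOX1, the superoxide-producing NADPH oxidase of colon epithelium, fell from 14.6 to 3.16 FPKM, the aldo-keto reductase AKR1B10 from 30.1 to 7.67, and the annexin ANXA13 from 9.86 to 2.11 (limma adjusted p = 0.00124, 0.00347 and 0.000139). Under the same rule and on the log2(FPKM + 1) scale, the largest rise was that of the C-type lectin CLEC3A. It rose from 37.3 ± 2.09 to 109 ± 12.4 FPKM (SD, n = 3 each), a log2 fold change of 1.51 ± 0.08 (SE, limma adjusted p = 0.000139). The thrombin receptor F2R rose from 21.5 to 51.4 FPKM, and the ephrin receptor EPHB6 from 4.21 to 10.9 (limma adjusted p = 0.000393 and 0.000814).

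In all, 1263 of the 13550 genes tested in HT29 passed the threshold (limma-trend with Benjamini-Hochberg adjustment), 628 higher and 635 lower in the knockout, and 377 passed without a filter on low values. The balance depended on the scale. Higher and lower genes numbered 719 and 520 on the TPM scale, 533 and 697 on the common median scale, and 820 and 949 after the GC and length correction. On the log2(FPKM + 1) scale 34 of the 1263 changed at least 2-fold, 10 higher and 24 lower (89 on the TPM scale and 130 with a pseudocount of 0.1), and the median absolute log2 fold change of the called genes was 0.39. The knockout and wild-type libraries did not overlap for 32.3% of the tested genes, where chance gives 10%. Among the 5 largest rises were also the neighbouring loci IGFL1P1 and IGFL2-AS1 on chromosome 19 (log2 fold changes 1.42 ± 0.29 and 1.30 ± 0.20, SE), the first of which lies inside the span of the second, so their reads are hard to tell apart. RPS10-NUDT3, the readthrough of RPS10 into NUDT3, was listed at 58.2 ± 28.7 FPKM in the wild type and 14.5 ± 0.826 in the knockout (SD, n = 3 each), and is uncertain because 81.9% of its exon bases are shared with NUDT3 and 17.8% with RPS10, which were not past the threshold (adjusted p = 0.0949 and 0.332). The count of called genes depended on single libraries: it was 360 without wild-type replicate 2, 378 without wild-type replicate 3, 513 without knockout replicate 1, 606 without knockout replicate 3 and 2231 without knockout replicate 2.

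Gene groups of the differentiated colon were lower in HT29 knockout cells. Of 12 tested genes of the goblet and secretory list, 7 fell and 1 rose (9 and 1 when adjusted over the list alone). They included the gel-forming mucin MUC5AC (from 2.66 to 0.706 FPKM), the disulfide isomerase AGR2 (from 59.0 to 36.3), the sialyltransferase ST6GALNAC1 (from 1.77 to 0.700) and SPDEF, a transcription factor of secretory cells (from 17.2 to 13.6). The exception was the trefoil peptide TFF2, which rose from 0.410 to 1.37 FPKM. The list lay below other genes (camera adjusted p = 7.5e-07; adjusted p = 0.13 with an estimated correlation), with a median log2 fold change of -0.52. Of 9 enterocyte genes, 5 fell and 2 rose, both over all genes and adjusted over the list alone. The actin-bundling villin VIL1 fell from 29.3 ± 0.545 to 17.2 ± 1.22 FPKM, galectin LGALS4 from 291 ± 17.3 to 179 ± 19.1 and carbonic anhydrase CA2 from 2.00 to 0.628 (SD, n = 3 each), while the keratin KRT20 rose from 95.1 to 175 FPKM. VIL1 shares 44.0% of its exon bases with USP37 on the opposite strand. This list also lay below other genes (camera adjusted p = 0.012, and adjusted p = 0.54 with an estimated correlation). The enterocyte list left the threshold when only genes with a mean of at least 1 FPKM were tested.

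Interferon-stimulated genes were the other large group to fall in HT29. Of 25 tested members, 10 fell and none rose (12 and 0 adjusted over the list alone), with a median log2 fold change of -0.25. The list passed camera (adjusted p = 7.5e-07) but not with an estimated correlation (adjusted p = 0.66) or by fry (adjusted p = 0.086). IFI6 fell from 106 ± 5.82 to 43.9 ± 15.0 FPKM, ISG15 from 119 ± 5.46 to 85.9 ± 6.97 and OASL from 11.6 to 8.54 (SD, n = 3 each). The factor IRF9, which carries the interferon signal to the nucleus, fell from 6.02 to 2.51 FPKM. Growth-related lists moved by smaller amounts. Of 24 MYC targets, 6 fell (12 over the list alone), NOP56, PA2G4 and BOP1 among them with log2 fold changes of -0.26, -0.24 and -0.34 (camera adjusted p = 1.6e-06; adjusted p = 0.24 with an estimated correlation). Of 24 ribosomal protein genes 1 fell, RPL3 (10 over the list alone, median -0.18, camera adjusted p = 7.9e-07; adjusted p = 0.66 with an estimated correlation), and on the common median scale none did and on the TPM scale 2. Of 24 nuclear genes of oxidative phosphorylation 2 fell, ATP5MC1 and ATP5F1B (8 over the list alone, median -0.16, camera adjusted p = 1.1e-06, and adjusted p = 0.66 with an estimated correlation). NOP56, PA2G4, BOP1, RPL3, ATP5MC1 and ATP5F1B all left the threshold without wild-type replicate 2, and each did so under further settings.

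The 2 cell-cycle lists went opposite ways in HT29. Of 22 G2/M genes, 6 rose and none fell (12 and 0 over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 1.9e-06; adjusted p = 0.54 with an estimated correlation). NUSAP1 rose from 25.2 to 34.0 FPKM, HMMR from 7.82 to 12.3 and the mitotic kinesin KIF20A from 15.0 to 19.2. Of 22 G1/S genes, 3 fell and none rose (5 and 0 over the list alone): cyclin E1 (CCNE1), the helicase subunit MCM6 and the flap nuclease FEN1, with log2 fold changes of -0.43, -0.32 and -0.24 (camera adjusted p = 0.002; adjusted p = 0.66 with an estimated correlation). FEN1 and MCM6 left the threshold under several other settings, and on the TPM scale 1 member of the list fell. CCNE1 left it without a filter on low values and without wild-type replicate 2, wild-type replicate 3 or knockout replicate 1. Fatty acid handling genes lay above other genes, with 5 of 18 higher and 1 lower (7 and 2 over the list alone; camera adjusted p = 0.015, adjusted p = 0.66 with an estimated correlation). PDK4, which restrains pyruvate oxidation, rose from 2.64 to 5.79 FPKM, the lipid droplet coat PLIN2 from 3.38 to 6.47 and CPT1A, the entry enzyme of fatty acid oxidation, from 23.0 to 28.5, while FABP1 fell from 1.07 to 0.427. Metallothioneins MT2A and MT1E rose, 2 of 5 tested in that list, both over all genes and over the list alone (camera adjusted p = 0.02; adjusted p = 0.6 with an estimated correlation, and 0.061 after the GC and length correction). None of the 10 called lists passed with an estimated correlation. Another division of the 6 HT29 libraries, with mixed groups, also called 10 lists. Fry, which asks whether a list's genes move 1 way on balance, called 7 lists, of which 5 were among the 10 called by camera, in the same direction. These were the goblet, enterocyte, MYC, G2/M and metallothionein lists. The interferon, ribosomal protein, oxidative phosphorylation, G1/S and fatty acid lists did not pass fry (fry adjusted p = 0.086, 0.18, 0.094, 0.2 and 0.062).

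In HCT116 the genes with the largest changes were other ones. The transcriptional coactivator CITED1 fell from 9.82 ± 1.59 to 0.516 ± 0.251 FPKM (SD, n = 3 each; log2 fold change -2.84 ± 0.14, SE, limma adjusted p = 4.26e-05). IRS4, an adaptor of insulin receptor signalling, fell from 4.36 to 0.0893 FPKM, and the neurofilament subunit NEFM from 3.54 to 0.0457 (limma adjusted p = 0.000146 and 2.13e-05). PEG10, an imprinted gene derived from a retrotransposon, rose from 6.08 ± 0.156 to 20.8 ± 1.39 FPKM (SD, n = 3 each; log2 fold change 1.62 ± 0.07, SE, limma adjusted p = 2.13e-05). The secreted Wnt antagonists DKK1 and DKK4 rose from 33.4 to 80.4 and from 0.834 to 3.79 FPKM (limma adjusted p = 0.000723 and 3e-04).

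In HCT116, 5021 of 13906 tested genes passed the threshold, 3558 higher and 1463 lower in the knockout, and 2040 passed without a filter on low values. On the log2(FPKM + 1) scale 51 changed at least 2-fold, 21 higher and 30 lower (187 on the TPM scale and 209 with a pseudocount of 0.1). The knockout and wild-type libraries did not overlap for 53.5% of the tested genes, where chance gives 10%. Rises were 70.9% of the calls on the deposited scale, 51.9% (2398 against 2224) on a common median scale, 47.3% (1480 against 1651) after a GC and length correction and 87.3% (5325 against 778) on the TPM scale, which raised the median log2 fold change of all tested genes by 0.123. After the GC and length correction 2304 of the 5021 calls kept their direction and significance. The count was 3323 without wild-type replicate 2 and 2645 without wild-type replicate 3. RN7SL2, an RNA of the signal recognition particle with near-identical copies, was listed at 28.7 ± 11.3 FPKM against 8.40 ± 2.67 (SD, n = 3 each) and is uncertain for that reason. The antisense RNA CD44-AS1 rose from 0.204 to 2.25 FPKM inside CD44, which rose from 45.1 to 64.7. Its exons share 14.3% of their bases with CD44 on the other strand, and the use of strand in counting is not given in the sources used here. PPAN-P2RY11, a readthrough that shares 54.4% of its exon bases with PPAN, was listed at 0.390 ± 0.675 against 4.29 ± 1.14 FPKM, and BEST1, which shares 14.2% with the ferritin gene FTH1 on the other strand, at 0.975 ± 1.22 against 5.98 ± 0.915 (SD, n = 3 each). Both are uncertain.

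Genes of the amino acid and stress response driven by ATF4 were lower in HCT116 knockout cells. Of 21 tested genes in the list of ATF4 targets and the unfolded protein response, 12 fell and 2 rose (14 and 2 over the list alone; camera adjusted p = 3.4e-07, adjusted p = 0.34 with an estimated correlation). Asparagine synthetase ASNS fell from 122 ± 2.22 to 77.3 ± 8.53 FPKM, the serine pathway enzymes SHMT2 from 83.2 to 53.1 and PHGDH from 39.8 to 24.7, and the amino acid transporter SLC7A5 from 222 to 136. The chaperone HSPA5 fell from 1559 ± 26.9 to 794 ± 24.9 FPKM (SD, n = 3 each; log2 fold change -0.97 ± 0.06, SE). Other chaperone genes of the same list went the other way: HSP90B1 rose from 362 to 455 FPKM and DNAJB9 from 15.0 to 23.1. The exons of ASNS share 44.6% of their bases with another listed gene on the same strand.

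Metabolic and redox lists were lower in HCT116 as well. Of 17 NRF2 targets 9 fell and 1 rose, with sulfiredoxin SRXN1 at 67.9 against 98.8 FPKM and transketolase TKT at 54 against 73.2 (camera adjusted p = 0.00027; adjusted p = 0.34 with an estimated correlation). Of 20 glycolysis genes 7 fell and none rose, ALDOA, GPI and GAPDH with log2 fold changes of -0.44, -0.41 and -0.32 (camera adjusted p = 5.8e-05; adjusted p = 0.34 with an estimated correlation). ALDOA shares 42.3% of its exon bases with another listed gene. In the ferroptosis and glutathione list 8 of 19 fell and 4 rose, among them the iron stores FTL (from 1549 to 975.1 FPKM) and FTH1 (from 818 to 552) and the lipid peroxidase GPX4 (from 121 to 88.5), while the lipid ligase ACSL4 rose from 7.65 to 13. The median of that list was 0.02 and its mean -0.11, and the test placed it below other genes (camera adjusted p = 0.037; adjusted p = 0.34 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 6 fell and none rose (10 over the list alone, camera adjusted p = 7.1e-06, and adjusted p = 0.34 with an estimated correlation). MT-ND1 fell from 3409 ± 202 to 2641 ± 116 FPKM, MT-ATP8 from 19720 to 15910 and MT-ATP6 from 18280 to 14970, the last pair overlapping by 46 bases. All of these left the threshold without a filter on low values. MT-ATP8 and MT-ATP6 also left it with the replicate number as a block and without wild-type replicate 2 or 3. MT-ATP6 further left it without wild-type replicate 1 or knockout replicate 3.

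Among ribosomal protein genes 11 of 24 fell in HCT116 and none rose (13 and 0 over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.47 with an estimated correlation), RPL7A and RPS2 with log2 fold changes of -0.38 and -0.44. Of 24 MYC targets 9 fell and 2 rose, SRM, RRP12 and BOP1 at -0.55, -0.46 and -0.52 (camera adjusted p = 0.0041; adjusted p = 0.34 with an estimated correlation). Of 24 nuclear oxidative phosphorylation genes 8 fell and 3 rose, UQCRC1, COX5A and NDUFV1 at -0.41, -0.31 and -0.36 (camera adjusted p = 0.0044; adjusted p = 0.56 with an estimated correlation). In the autophagy and lysosome list 7 of 23 fell and 3 rose (camera adjusted p = 0.02; adjusted p = 0.34 with an estimated correlation), with the autophagy receptor SQSTM1 at 59.7 against 95.6 FPKM. Epithelial junction genes split, with 5 of 22 lower and 3 higher (camera adjusted p = 0.013; adjusted p = 0.34 with an estimated correlation). Among them CLDN7 fell from 97.6 to 53.3 FPKM and desmoplakin DSP rose from 26.6 to 38.5. In the mesenchymal list 1 of 14 fell, vimentin (VIM, from 9.63 to 3.59 FPKM) and 1 rose (camera adjusted p = 0.038; adjusted p = 0.56 with an estimated correlation). Both these lists left the threshold after the GC and length correction (adjusted p = 0.18 and 0.38). The scale moved these counts. On the TPM scale the lower and higher members were 5 and 1 for ribosomal proteins, 3 and 0 for mitochondrially encoded mRNAs, 3 and 1 for glycolysis, 6 and 5 for MYC targets, 4 and 5 for nuclear oxidative phosphorylation, 4 and 6 for autophagy and lysosome and 3 and 5 for epithelial junctions. On the common median scale they were 16 and 0, 11 and 0, 12 and 0, 11 and 1, 11 and 0, 9 and 1, and 9 and 1, in the same order, and 5 and 0 for the mesenchymal list. After the GC and length correction they were 16 and 0, 13 and 0, 7 and 0, 9 and 0, 12 and 0, 7 and 0, and 7 and 2, again in that order, and 11 and 1 for the ferroptosis list. On the TPM scale the medians of 4 called lists (MYC targets, epithelial junction, mesenchymal, autophagy and lysosome) were no longer below 0, and on the common median scale that of the ferroptosis list was. On the common median scale the m6A, ferroptosis, sterol and mesenchymal lists left the threshold (camera adjusted p = 0.062, 0.057, 0.057 and 0.058). No called list changed its side relative to other genes on either scale.

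Wnt targets were higher in HCT116 knockout cells. Of 16 tested Wnt targets and intestinal stem cell genes 11 rose and none fell, both over all genes and over the list alone, with a median log2 fold change of 0.37 (camera adjusted p = 0.0013; adjusted p = 0.34 with an estimated correlation). AXIN2, a feedback inhibitor used as a readout of Wnt signalling, rose from 3.66 to 6.81 FPKM, SP5 from 0.860 to 2.43, BMP4 from 26.7 ± 2.08 to 41.6 ± 0.701 and SOX9 from 42.3 ± 1.18 to 59.2 ± 3.49 (SD, n = 3 each). Genes of sterol and fatty acid synthesis were also higher, with 13 of 24 risen and 2 fallen (camera adjusted p = 0.037; adjusted p = 0.5 with an estimated correlation), a call that was lost on the common median scale and in 1 fit for both lines. The isomerase IDI1 of the mevalonate pathway rose with a log2 fold change of 0.80, while DHCR7 fell from 26.1 to 17.2 FPKM. In the list of m6A writers, erasers and readers 11 of 24 rose and 1 fell, 17 and 1 on the TPM scale and 4 and 1 after the GC and length correction (camera adjusted p = 0.037; adjusted p = 0.56 with an estimated correlation, and 0.18 after the GC and length correction). The writer subunit METTL14 rose from 2.38 to 4.15 FPKM and the reader YTHDF3 from 6.57 to 10.2. The reader IGF2BP1 fell from 1.97 ± 0.0882 to 0.269 ± 0.0580 (SD, n = 3 each), and the catalytic subunit METTL3 (2.76 against 2.50) and the other m6A eraser ALKBH5 (31.0 against 31.8) did not pass the threshold. None of the 14 called lists passed with an estimated correlation, and fry called 17 lists, of which 10 were among these 14 in the same direction. The ribosomal protein, nuclear oxidative phosphorylation, epithelial junction and mesenchymal lists did not pass fry (fry adjusted p = 0.062, 0.23, 0.068 and 0.23).

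**Figure D2:**
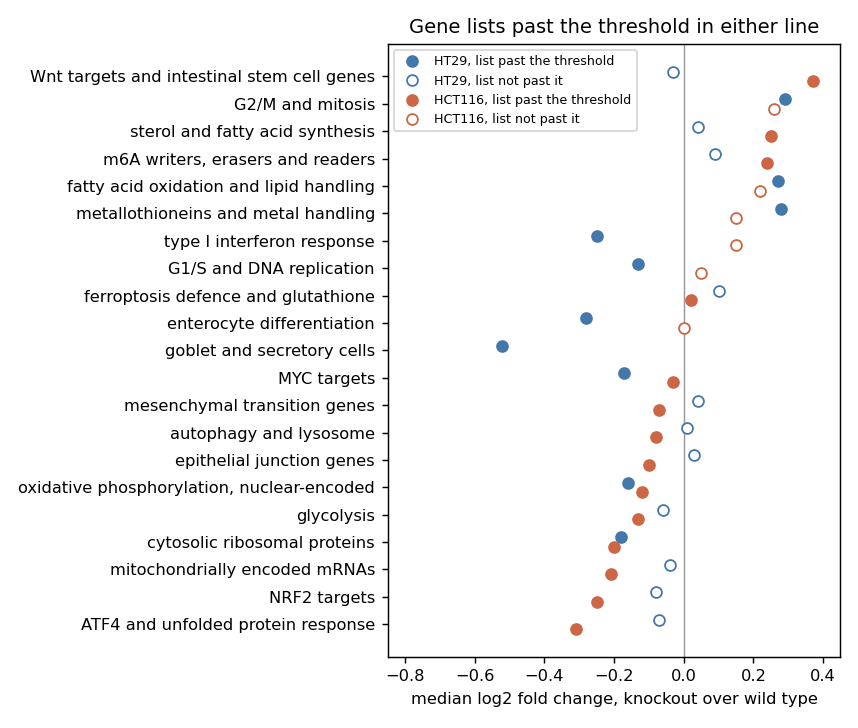
Median log2 fold change of FPKM + 1, knockout over wild type (horizontal axis), of the tested genes of each list that passed the threshold in either line (vertical axis). Blue is HT29 and orange HCT116. Filled points passed camera with the preset correlation, and no filled point passed with an estimated one. The goblet and secretory list, at -0.52, was tested in HT29 and not in HCT116, where it had too few expressed members.

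The lists for fibroblasts and for endothelium and blood had too few expressed genes to test in either line, and the leukocyte list was past the threshold in neither (adjusted p = 0.76 in HT29 and 0.82 in HCT116). Genes beside FTO on chromosome 16, tested because editing can disturb neighbours, did not pass camera as a list (adjusted p = 0.76 in HT29 and 0.088 in HCT116), but fry called them higher in HCT116 (adjusted p = 0.024). Of 8 tested in HT29 1 fell, TOX3, and of 6 in HCT116 3 rose, RBL2, LPCAT2 and CHD9, in a list whose transcripts have a median GC content of 41.1%.

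Whether the lines responded differently was tested as the difference between their fold changes. CXCR4 stood out first: it fell in HT29 from 16.9 to 1.96 FPKM and rose in HCT116 from 2.05 to 2.65, a difference of log2 fold changes (HCT116 minus HT29) of 2.86 ± 0.09 (SE, limma adjusted p = 1.08e-08). DKK1 fell in HT29 from 22.5 to 7.04 FPKM and rose in HCT116 from 33.4 to 80.4 (difference 2.80 ± 0.14, SE, adjusted p = 5.07e-07). The growth factor FGF9 fell in HT29 from 1.09 to 0.410 and rose in HCT116 from 1.08 to 3.66. PEG10, CITED1, IRS4 and the ubiquitin hydrolase UCHL1 changed in HCT116 and had group means of at most 0.228 FPKM in HT29, and ANXA13 was the reverse, with at most 0.0478 FPKM in HCT116, so these differences follow which line expresses the gene. The cytidine deaminases APOBEC3C and APOBEC3G differed in the other direction, with log2 fold changes of 0.97 and 0.80 in HT29 and 0.06 and -0.62 in HCT116. In all 1192 of 14320 genes tested passed, 762 with the higher fold change in HCT116 and 430 with the lower. Of these, 91 were called in both lines separately, 65 of them in opposite directions. The count was 700 without HCT116 wild-type replicate 3, 709 without HT29 wild-type replicate 1, 756 without HCT116 knockout replicate 1, 773 without HT29 knockout replicate 2, 782 without HT29 wild-type replicate 2 and 783 without HCT116 wild-type replicate 2.

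Of 31 lists tested for the difference 11 passed with the preset correlation. With an estimated correlation 1 did, the goblet and secretory list (9 tested, 6 past the threshold and all 6 with the higher fold change in HCT116; adjusted p = 0.028 with an estimated correlation), in which HCT116 expresses few members. The type I interferon list fell in HT29 and not in HCT116, where 4 of 15 rose and 2 fell. In HCT116 alone camera did not call this list (camera adjusted p = 0.8), and fry called it higher (fry adjusted p = 0.0041). Its difference between the lines passed (median 0.41, camera adjusted p = 0.00022, and adjusted p = 0.41 with an estimated correlation). The ATF4 and unfolded protein response list differed by a median of -0.25 (camera adjusted p = 8.3e-09; adjusted p = 0.15 with an estimated correlation) and the Wnt list by 0.30 (camera adjusted p = 0.00022; adjusted p = 0.087 with an estimated correlation). In HT29 the Wnt list had 2 members that rose, NKD1 and BMP4, and 3 that fell, EPHB3, CD44 and MYC.

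A set of genes moved the same way in both lines. MYO1C, an unconventional myosin, fell from 53.3 ± 1.87 to 25.8 ± 1.25 FPKM in HT29 and from 43.8 ± 3.4 to 17.6 ± 1.33 in HCT116 (SD, n = 3 each). HSPA5 fell from 126 to 72.5 FPKM in HT29 as well, again beside rises of HSP90B1 (from 115 to 163) and DNAJB9 (from 3.58 to 6.48). The arginine methyltransferase CARM1 fell from 17.7 to 8.35 FPKM in HT29 and from 22.6 to 11.8 in HCT116, and ezrin (EZR), which links actin to the membrane, from 91.2 to 58.3 and from 499 to 309. CARM1 shares 19.9% of its exon bases with YIPF2 on the other strand. FTO was among the 5 strongest shared falls. Among the strongest shared rises were the ectonucleotidase NT5E (1.63-fold in HT29, 1.51-fold in HCT116), the pyrophosphate exporter ANKH (1.36-fold and 1.58-fold), the semaphorin SEMA3C (1.67-fold and 2.02-fold) and the GTPase RHOU (2.25-fold and 1.70-fold). The limma adjusted p of these 9 genes ran from 0.000108 to 0.00407 over both lines.

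Of 11999 genes tested in both lines, 227 fell in both where independent lists would share 60.3, and 281 rose in both where they would share 145.4 (Fisher's exact test, two-sided, p = 3.7e-80 and 1.8e-36; genes are not independent replicates). Another 65 went opposite ways, against 205.6 for independent lists. Across these genes the log2 fold changes of the lines had a Pearson r of 0.41 and a Spearman rho of 0.49, and r was 0.31 once the trend of each with GC content was removed. The lines have separate wild-type libraries, so no control is shared. Of the 227 shared falls, 195 were called in both lines after the GC and length correction too. Among the 210 of them with an annotated 3′ UTR, 14 carried the 7-base word ATCTCGA there, where 2.2 were expected from UTRs of like length and GC content. EZR and HSPA5, and also NT5E, which rose, carried the overlapping word TCTCGAA. The count of 508 shared genes was 96 without a filter on low values, 776 with the replicate number as a block and 801 in 1 fit for both lines. With 1 library left out it ran from 137 (without HT29 wild-type replicate 2) and 141, 188 and 226 (without HT29 wild-type replicate 3, knockout replicate 1 or knockout replicate 3) to 1132 (without HT29 knockout replicate 2).

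**Figure D3:**
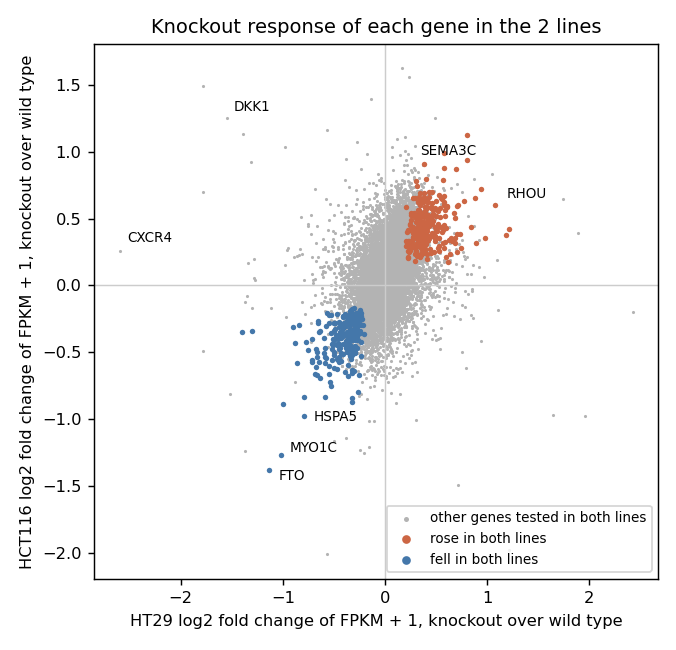
Log2 fold change of FPKM + 1, knockout over wild type, in HT29 (horizontal axis) and HCT116 (vertical axis) for the 11999 genes tested in both lines, 1 point per gene. Orange points rose (281) and blue points fell (227) past the threshold in both lines. FTO lies at -1.13 and -1.37, and MYO1C and HSPA5 lie near it.

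Fold changes followed the GC content of the transcripts in both lines, more steeply in HCT116. In HCT116 the median log2 fold change ran from 0.36 for 469 genes under 38% GC to -0.09 for 3350 genes of 58% or more (Spearman rho across genes -0.60). In HT29 it ran from 0.15 to -0.04 (rho -0.32). This slope stands beside every HCT116 count above, and lists of low GC content, such as the m6A list (median 45.4%) and the G2/M list (45.0%), lie on its rising side.

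**Figure D4:**
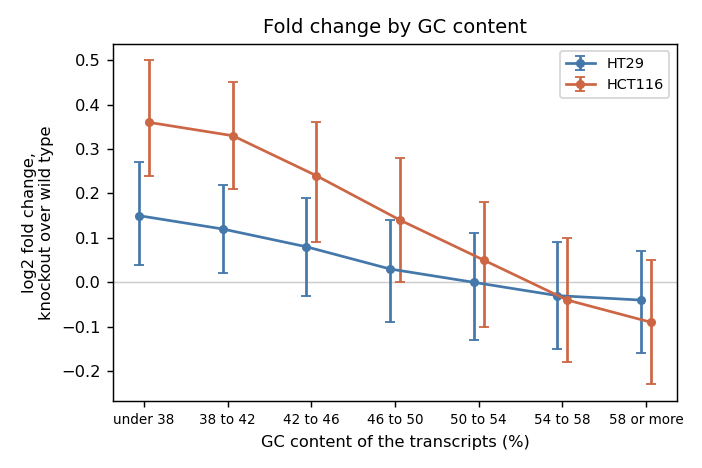
Median log2 fold change of FPKM + 1, knockout over wild type (vertical axis), of the tested genes in 7 classes of GC content of their transcripts (horizontal axis, percent). Blue is HT29 and orange HCT116, and whiskers span the quartiles. Medians fall from 0.15 to -0.04 in HT29 and from 0.36 to -0.09 in HCT116.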

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

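Of the tests in this part, those of the GC trend as the whole cause of the HCT116 calls, of the FPKM scale behind the excess of rises, of GC trends within HT29 groups, of the excess on the X chromosome, of the short sequence in genes not selected for falling and of the short sequence in the FTO message were chosen after the result was seen.

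A test of the difference between the responses of the lines (HCT116 minus HT29) marked 10 genes under the naming rule. The difference was 2.86 for CXCR4, 1.76 for PEG10, 2.80 for DKK1, 1.73 for FGF9 and 1.75 for ANXA13, and it was -2.72 for CITED1, -2.28 for IRS4, -1.77 for UCHL1, -0.91 for APOBEC3C and -1.42 for APOBEC3G. The same test marked 11 lists, with median differences of -0.25 for ATF4 and the unfolded protein response, 0.70 for goblet and secretory cells, -0.16 for mitochondrially encoded mRNAs, 0.41 for type I interferon, 0.30 for Wnt targets, -0.19 for epithelial junctions, -0.11 for autophagy and lysosome, -0.35 for ferroptosis and glutathione, -0.16 for NRF2 targets, -0.11 for glycolysis and -0.10 for p53 targets. The p53 list left the threshold after the GC and length correction (adjusted p = 0.083). With an estimated correlation only the goblet and secretory list passed among these 11 (adjusted p = 0.028). Of 100 drawn splits of the libraries within each line, 4 gave as many genes as the real 1192, the real one included. The highest other, 6000, kept the division of HT29 and swapped the groups of HCT116, and 5378 and 1354 kept the real division of HCT116 with mixed HT29 groups, so these counts reflect the response within the lines and the share does not exclude chance for a difference between them.

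In HT29, 10 splits of 6 libraries cannot give a share under 0.05: the real split called 1263 genes, 34 of them at least 2-fold, and 10 lists, and the highest other split called 4, 4 and 10. The real value was reached by 1 split for each of the gene counts and by 2 for the lists. In HCT116 the real split called 5021 genes, 51 at least 2-fold and 14 lists, the highest other 3, 3 and 10, and 1 split reached each, again with too few splits for a share under 0.05. Mixed splits called 2 to 10 lists in HT29 and 0 to 10 in HCT116, with almost no called genes. Each side of a mixed split still held more libraries of 1 genotype. The number of lists called in HT29 therefore does not set the real division apart. For the genes called in both lines in the same direction, 1 of 100 drawn splits, the real one, gave as many as 508. The highest other, 65, kept the division of HT29 and swapped the groups of HCT116. Mixed groups called at most 4 genes in HT29 and 3 in HCT116, so such splits had almost no genes to share. The share therefore speaks against a chance division of the libraries within the lines. It does not decide whether the lines share a response.

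The HCT116 calls followed GC content. A trend over annotated GC content as the whole cause is argued against by 2304 of the 5021 genes. These kept direction and significance after each library's trend was removed. Whether the FPKM scale gives the excess of rises over falls stays open: the share of rises was 51.9% on a common median scale, which evens the split by centring, and 87.3% on the TPM scale. GC trends also varied between libraries of 1 group, with a largest range of 0.72 in the Spearman rho within an HT29 group (0.22 and -0.50 in knockout replicates 2 and 1). In HCT116 the rho divided by genotype, at 0.34 to 0.64 in wild type and -0.63 to -0.29 in knockout, and such variation in preparation stays open as a source of small fold changes in both lines. A response of low-GC genes to the loss of FTO was not told apart from it.

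The 227 genes that fell in both lines included MYO1C, HSPA5, CARM1 and EZR. A trend over annotated GC content as their cause is argued against. After the correction 85.9% still fell past the threshold in both lines. The 3′ UTR word ATCTCGA was in 14 of 210 (C17orf58, MCU, BNIP3L and CLDN7 among them; z = 8.16), and 0 of 100 matched sets had a best word as enriched, the highest reaching 6.17. Among 184 tested genes with the word that had not fallen in both lines, the mean log2 fold change was -0.02 in HT29 and 0.11 in HCT116. The matched means were 0.07 and 0.18, and 0 of 1000 matched sets were as low in either line. The sets were matched on the length and GC content of the 3′ UTR. They were not matched on the GC content of the whole transcript, which fold changes followed, so its part in these shifts was not tested. For the 64 of them with the longer word ATCTCGAA, the means were 0.01 and 0.15 against matched means of 0.07 and 0.2. Of 1000 matched sets 2 in HT29 and 11 in HCT116 were as low. Genes with the longer word thus also lay below matched genes, though not below the 184 genes with the 7-base word. The longer word lies in 12 of 23 annotated FTO transcripts, in exon 4 of 9 (chromosome 16, 53844185 to 53844192, GRCh38). Of 192 other genes of like transcript length, 8 hold it and 25 hold the 7-base word. BNIP3L and CLDN7 carry only the 7-base word. The best word of the HT29 falls was TCGAATC, which is not the same word but shares the bases TCGAA with ATCTCGAA. It ranked 1379 among genes that fell in HCT116 alone, which decides nothing. A candidate explanation is a short hairpin RNA against FTO whose seed also lowers other messages. The table titles would allow it and the labels contradict it. An effect of FTO itself stays open, as the 3′ UTRs of MYO1C, HSPA5, CARM1 and EZR all lack ATCTCGA. HSPA5 and EZR carry the overlapping TCTCGAA, as does NT5E, which rose.

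The genes that fell at least 2-fold in HCT116 were tested for loss of surrounding DNA, with 29 of the 30 examined. A loss reaching 1 Mb around most of them is argued against by 451 tested neighbours within that distance. Their median log2 fold change was 0.02 (95% interval -0.015 to 0.053), against 0.094 for all tested genes. The neighbours were pooled and left out genes that themselves fell at least 2-fold. A shorter loss, or a loss at a few of the genes, could not be detected this way and stays open. Of the 29, 6 were on the X chromosome, CITED1 and IRS4 among them (20.7% against 3.1% of tested genes; odds ratio 8.21, 95% interval 2.72 to 20.9; Fisher's exact test, two-sided, p = 0.00023), as were 3 of 24 in HT29. A difference between the cells chosen for the knockout and the wild-type culture may lie behind that excess and was not tested.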

How the results depend on the processing

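The removal of the GC and length trend and the TPM scale were chosen after the data were seen. No named gene, no list past the threshold and no FTO value reversed. The balance of rises and falls did turn. In HCT116 it was 3558 against 1463 as reported and 1480 against 1651 after the GC and length correction. In HT29 it was 628 against 635 as reported and 719 against 520 on the TPM scale. The HT29 balance leaned the other way on the common median scale (533 against 697) and after the GC and length correction (820 against 949). Over all settings 141 summary values stayed the same and 39 moved; among the lists 308 values kept their side of the threshold and 51 did not, among the genes named within lines 891 and 84, and among those named for the difference 190 and 0. Without a filter on low values 377 genes passed in HT29, 2040 in HCT116 and 96 in both lines, with r between the lines at 0.313; more genes were tested. With a pseudocount of 0.1, which raises fold changes of low genes by construction, 130 and 209 genes were at least 2-fold in HT29 and HCT116, r was 0.351, and FTO stood at -2.62 and -2.78. On the TPM scale, which enlarges the values before 1 is added, 89 and 187 were at least 2-fold. With an estimated correlation 0 lists passed in HT29 and 0 in HCT116. The GC and length correction left 3131 genes in HCT116 and r at 0.298. In 1 fit for both lines 801 genes passed in both lines; the cause was not tested.

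With the replicate number as a block (replicate block), 776 genes passed in both lines, 1746 in HT29, 4895 in HCT116 and 1197 for the difference; the cause was not tested. Deviations of libraries with the same number correlated at 0.20, 0.16 and -0.12 in HT29 and 0.08, -0.11 and 0.09 in HCT116. The wild-type library matched its own number best in 2 of 3 and 1 of 3. With 3 libraries per group this does not decide whether the numbers pair the libraries.

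With 1 library left out, HT29 calls ran from 360 to 2231, those at least 2-fold from 34 to 46, lists from 10 to 12 and FTO from -1.17 to -1.08. HCT116 calls ran from 2645 to 4692, those at least 2-fold from 50 to 72, lists from 12 to 16 and FTO from -1.41 to -1.32. The difference ran from 700 to 1249 genes, the shared genes from 137 to 1132 and r from 0.327 to 0.484. These counts rest on fewer libraries and on single ones: HT29 wild-type replicate 2 gave 360 and 137 when left out, HT29 knockout replicate 2 gave 2231 and 1132, and HCT116 wild-type replicate 3 gave 2645 and 700. FTO had no value in HT29 at a mean of at least 1 FPKM, where it was not tested. Alternatives that need counts were not run, as the values used here are FPKM.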

Other observations

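Among HCT116 lists that did not pass camera on the deposited scale, immediate early and MAPK feedback genes had many members that rose; these genes were chosen after their values were seen. Of 20 tested immediate early genes 10 rose and 3 fell (camera adjusted p = 0.21, fry adjusted p = 0.0041; adjusted p = 0.56 with an estimated correlation, and camera adjusted p = 0.00065 after the GC and length correction), with the serum-induced factors FOS at 26 ± 1.27 against 12.2 ± 1.04 FPKM and EGR2 at 7.94 ± 1.00 against 3.24 ± 0.329 (SD, n = 3 each). Of 18 MAPK feedback genes 9 rose and 4 fell (camera adjusted p = 0.21, fry adjusted p = 0.0041; adjusted p = 0.52 with an estimated correlation), among the rises the ERK phosphatase DUSP6 (257 against 163.7 FPKM), SPRY4 (39.9 against 25.6) and the EGFR ligand EREG (83.2 against 50.6). In HT29 none of FOS, DUSP6, SPRY4 and EREG passed the threshold (limma adjusted p = 0.515, 0.622, 0.647 and 0.2).

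The p53 targets split in HCT116, with 7 of 21 higher and 6 lower (camera adjusted p = 0.16; adjusted p = 0.5 with an estimated correlation). The stress cytokine GDF15 fell from 295 ± 23.9 to 169 ± 14.7 FPKM and the cell-cycle inhibitor CDKN1A from 139 ± 9.25 to 103 ± 4.67, while RRM2B rose from 8.15 to 13.5 and MDM2, which marks p53 for degradation, from 5.92 to 8.32 (SD, n = 3 each).

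The authors' deposited tables mark 327 genes in HT29 (158 higher, 169 lower) and 812 in HCT116 (413 higher, 399 lower), all with q under their threshold and at least 2-fold. Of the genes marked in the authors' deposited tables, 148 and 221 were tested here, and 129 and 212 of those were called here in the same direction.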
